A study of Homo sapiens with 4 samples.

How the data were processed

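Total RNA from 4 transfections of HCT116, an established human colon cancer cell line, was measured on Affymetrix expression arrays, with 1 array per group. Cells received either the empty plasmid pcDNA3.1, the same plasmid carrying the primary transcript of the microRNA miR663a, a scrambled control RNA or an inhibitor of miR663a, the last pair being single-stranded RNAs. Per the labels' protocols, RNA was extracted with Trizol and biotinylated cRNA was prepared from 250 ng of total RNA. The design text gives the aim as a search for genes lowered by miR663a overexpression and raised by its inhibition.

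Groups were taken from the source, description and genotype labels of each array, which give the same assignment. The titles of the RNA arrays read the other way round, with the title for an inhibitor on the scrambled control array and the title for a control on the inhibitor array. The header of the authors' deposited table describes its second ratio as inhibitor over control, and that ratio correlated at 1 with the assignment used here and at -1 with the turned one. The turned sign was computed as an alternative.

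A value table deposited by the authors holds log2 values of 16381 probe sets on each of the 4 arrays. The submitters' processing notes name MAS5 and no version. The background correction and the normalization between arrays are not given in the sources used here. A further table deposited by the authors gives linear ratios of overexpression over vector and of inhibitor over scrambled RNA for 42450 probe sets, with a score column that equals the sum of squared deviations of the 4 log2 values. Of these probe sets, 12704 were also in the value table, and 3677 probe sets of the value table had no row in the ratio table. For shared probe sets the log2 of the authors' ratios differed from the differences in the value table by at most 9.87e-05 for overexpression and 9.83e-05 for the inhibitor. The genome build of the positions in the authors' table is not given in the sources used here.

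Probe sets were named through RefSeq accessions in a gene table of assembly GRCh38.p14, used for names only. Accessions named 38798 probe sets, current symbols 648 and older symbols 343. The file's own symbol was kept for 1699 probe sets, 961 named several genes and were left out of all gene counts, and 1 had no name. Spreadsheet conversion had turned the symbol of 59 probe sets into whole numbers, and 58 of them were named through RefSeq. This gave 8794 genes with levels and 20245 genes with ratios. In the value table each gene was taken by its probe set with the highest mean log2 value over the 4 arrays.

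Detection calls were not used here. A gene was counted in a comparison when its value lay above the median of all probe sets on both arrays. A gene above that median on 1 array only was counted apart. With 1 array per group there is no replicate check, and no test, standard error or p-value was computed between groups. The number of arrays limits the precision, and every count rests on single arrays. Genes were counted past a fixed 2-fold difference and past 1.5-fold. The 2 comparisons of the design share no array. The difference between the scrambled RNA and vector arrays was computed as background.

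Before the data were examined, 23 gene lists were fixed, together with the rule for named genes. That rule takes the microRNA locus and TTC22, the 12 largest rises and falls per comparison, up to 12 genes past 1.5-fold in opposite directions, up to 4 members of each list by size of ratio, and all measured genes of a list of miR-663 targets from the literature. A few genes that the rule takes are not reported here. Genes named outside the rule are described as chosen after their values were seen. A list's median log2 ratio was set among 10000 random lists of the same size matched on mean signal in 20 bins, where at least 5 members were measured. For the authors' ratio table, which has no levels, random lists were matched on the number of probe sets and not on signal. Median overexpression log2 ratios fell from 0.09 in the dimmest of 5 groups of genes to -0.08 in the brightest, so percentiles from that table can carry an effect of signal. The percentile describes these arrays and is no test of the transfections. Lists under the 2.5th or over the 97.5th percentile are reported as outside the range of random lists.

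Alternatives were centring of each array on its median, quantile normalization, no filter on dim genes, a stricter filter, an offset of 64 on the linear scale, the mean of all probe sets of a gene, 50 signal bins, the other threshold and the turned sign. The counts from the authors' ratio table, per probe set and per gene, were added after the data had been seen. Sequences of 3′ untranslated regions were not used here, so the planned comparison of genes with miR-663a seed sites was not run.

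Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The calculation was tested on simulated data for the overexpression comparison with 5510 genes. It called 75% of genes changed by 1.2 log2 units and 100% of genes changed by 2 log2 units past 2-fold, and 0 unchanged genes. All lists shifted by 0.3 log2 units lay above the 97.5th percentile, and 8% of 100 unshifted lists lay outside the range of random lists, where 5% would be expected. The simulated noise was independent between genes and of 1 size at all signal levels. List shifts under 0.3 log2 units were not simulated, so how often smaller ones are found is not known.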

Results

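Gene expression was measured in HCT116 colon cancer cells after 4 transfections, with 1 array each for the vector control, miR663a overexpression, the scrambled RNA control and the miR663a inhibitor. The arrays had closely similar distributions. Their median log2 values were 4.12 for vector, 4.19 for overexpression, 4.16 for scrambled RNA and 4.16 for the inhibitor. Across probe sets, pairs of arrays correlated between 0.9945 (overexpression and inhibitor) and 0.9967 (scrambled RNA and inhibitor). There were no replicates, so no difference below could be set against a spread between arrays of a group.

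All ratios are given as overexpression over vector and as inhibitor over scrambled RNA. The sample titles of the RNA arrays contradict the other labels, and with those titles every inhibitor ratio would turn its sign. The mature microRNA was not analysed here, so its level checks neither transfection. LOC284801, which the authors' deposited table places in the band 20p11.1, had ratios of 0.878, 0.990 and 1.31 with overexpression on its 3 probe sets, and 0.939, 1.01 and 0.951 with the inhibitor. The probe set with the ratio of 1.31 is listed on chromosome 7. TTC22, which encodes a tetratricopeptide repeat protein and was named in advance, lies on chromosome 1 and had 4 probe sets in the authors' deposited table. Their overexpression ratios were 1.32, 1.07, 1.22 and 1.10, and their inhibitor ratios in the same order were 0.834, 0.890, 0.900 and 1.06. No TTC22 ratio reached 1.5-fold in either direction.

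The first comparison asked which transcripts differed when miR663a was overexpressed. Few did by 2-fold. Of 5510 genes counted, 3 were at least 2-fold higher and 2 at least 2-fold lower. AHNAK2, which encodes a large scaffold protein, was 2.23-fold lower, and IL18, a cytokine of the interleukin-1 family, was 2.04-fold lower. On the overexpression array AHNAK2 was at 4.52, near the array median of 4.19, and IL18 at 8.39. MAPK12, the p38 gamma kinase, was 2.23-fold higher, the uncharacterised LOC441461 was 2.14-fold higher, and CACNA1A, the pore subunit of a neuronal calcium channel, was 2.13-fold higher.

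Below these, the lowest genes with overexpression included CEP57, a centrosomal protein, at 1.99-fold lower, ZNF280D at 1.89-fold lower, HACD1, an enzyme of very long chain fatty acid synthesis, at 1.87-fold lower and NOCT at 1.85-fold lower. SOCS6, a suppressor of cytokine signalling, was 1.85-fold lower, and the nuclear long noncoding RNA MALAT1 was 1.81-fold lower. The highest genes included LLGL1, a regulator of cell polarity, at 1.88-fold higher, CFAP410 at 1.80-fold, MATN1, a cartilage matrix protein, at 1.73-fold, TSSK3, a testis kinase, at 1.72-fold, ANK1 at 1.72-fold and LRRC32 at 1.71-fold. On the vector array LRRC32 was at 4.19 and ANK1 at 4.42, near the array median of 4.12. At 1.5-fold, 51 genes were higher and 90 lower. That split depended on scaling and on the filter: 109 were higher and 49 lower after each array was centred on its median, 52 and 59 after quantile normalization, 169 and 122 with no filter on dim genes, and 4 and 20 with the offset of 64. A further 259 genes lay above the array median on 1 of the arrays only, 1 of them with a difference of at least 2-fold from that median.

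Medians of the other probe sets of these genes were smaller, though MALAT1 probe sets reached log2 ratios as low as -1.77. In the authors' deposited table the remaining probe set of AHNAK2 had a log2 ratio of -0.22 against -1.16 on the probe set used, that of MAPK12 had 0.15 against 1.16, and the remaining 4 of CEP57 had a median of -0.28 against -0.99. The remaining 2 probe sets of SOCS6 had a median of -0.56 against -0.88, and the 11 of MALAT1 a median of -0.69 against -0.86. That of TSSK3 went the opposite way, at -0.15. IL18 had no other probe set. Across 1352 genes with a second probe set above the median on all arrays, the overexpression log2 ratios of the 2 probe sets correlated at 0.302, and their difference had a standard deviation of 0.28 across genes.

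Among gene lists, 3 of 18 lay above the range of random lists with overexpression and 0 below it. The immediate early and AP-1 genes had a median log2 ratio of 0.04 over 20 measured genes, at percentile 99.7. FOSB was at 0.37 and FOSL2 at 0.26, while EGR3 was at -0.46. The hypoxia and glycolysis genes had a median of 0.02 over 20 genes, at percentile 98.6, with the carbonic anhydrase CA9 at 0.43 and PFKFB4 at 0.34, and SLC2A3 at -0.38. The published miR-663 targets had a median of 0.05 over 10 genes, at percentile 98.3. Of these, 7 lay above 0, among them FOSB at 0.37 and PIK3CD at 0.35, and those below 0 were HMGA2 at -0.38, JUND at -0.18 and EEF1A2 at -0.05. The other probe sets of FOSL2 had a median of -0.09 and that of PIK3CD was at -0.32, opposite to the values used. No member of these 3 lists passed 1.5-fold. After quantile normalization the AP-1 genes lay at percentile 97.0 and the published targets at 96.9, and with the mean of all probe sets of a gene the published targets lay at 94.7. Over all genes of the authors' deposited table, with random lists not matched on signal, the 3 lists lay at 61.5, 21.6 and 77.0.

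The remaining lists lay inside the range of random lists with overexpression in the main analysis, some of them near its edge. The TGF-beta response genes were at percentile 4.24 with a median of -0.18, with the inhibitory SMAD7 at -0.60 and thrombospondin, THBS1, at -0.45, though the remaining 4 probe sets of THBS1 had a median of 0.06. The microRNA pathway genes were at 3.83 with a median of -0.16, and their member DICER1, the enzyme that cuts microRNA precursors, was 1.53-fold lower on 1 probe set, while its remaining 5 had a median log2 ratio of -0.06 with 3 of them below 0. The endoplasmic reticulum stress and amino acid response genes were at 8.16 with a median of -0.14, with DNAJC3 at -0.64, TRIB3 at -0.59 and XBP1 at -0.50, whose remaining probe set was at 0.06. Under some of the alternatives fixed in advance these 3 lists crossed the lower edge. The TGF-beta genes lay at 1.74 with no filter on dim genes, at 1.67 with the offset of 64 and at 0.515 with the mean of all probe sets, the microRNA pathway genes at 0.45 with the offset and 2.39 after quantile normalization, and the stress list at 0.37 with the mean of all probe sets. Over all genes of the authors' deposited table, with random lists not matched on signal, they lay at 11.7, 48.9 and 0.07, with medians of -0.07, -0.02 and -0.15. Medians and percentiles were -0.10 and 28.7 for the cell cycle, -0.12 and 10.8 for the interferon response, -0.10 and 17.2 for epithelial-mesenchymal transition and invasion, and -0.11 and 37.1 for Wnt targets. They were -0.05 and 41.5 for ribosomal proteins, -0.06 and 55.6 for oxidative phosphorylation, -0.05 and 47.4 for histones, -0.03 and 74.7 for p53 targets and -0.01 and 86.9 for heat shock genes. They were 0.01 and 95.6 for cholesterol synthesis, 0.04 and 93.0 for NF-kB and inflammation, and 0.10 and 89.8 for colon epithelial differentiation, of which the first lay at 97.6 after quantile normalization and 71.2 with the mean of all probe sets, and the last at 98.9 with no filter. Centring or quantile normalization turned the sign of 5 and 8 of the 18 medians, so these values order the lists against each other and give no direction of their own.

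Markers of other cell types were measured for few genes in this cell line. The leukocyte markers counted with overexpression were dim, from 4.39 for CD3E to 5.32 for CD79A on the vector array, whose median was 4.12. With overexpression all 4 leukocyte markers counted lay above 0, with a median of 0.37, the 2 endothelial markers had a median of 0.28, and the 4 fibroblast markers a median of -0.14, with decorin, DCN, 1.57-fold higher on a probe set near the cutoff (4.13 on the vector array), while its remaining 4 had a median log2 ratio of 0.10. TUBB3, the only neural or hepatocyte marker counted, was at 0.17 with overexpression and -0.20 with the inhibitor. With the inhibitor the 5 leukocyte markers had a median of -0.14, at percentile 10.4, the endothelial markers a median of 0.19 and the fibroblast markers a median of 0.15.

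The second comparison asked which transcripts differed when miR663a was inhibited. Of 5488 genes counted, 1 was at least 2-fold higher and 0 were at least 2-fold lower. PPP1CB, a catalytic subunit of protein phosphatase 1, was 2.28-fold higher with the inhibitor. RBL1, the retinoblastoma-related protein p107, was 1.96-fold higher, the zinc finger gene ZNF623 was 1.83-fold higher, and ACSL4, an acyl-CoA ligase that prefers arachidonate, was 1.82-fold higher. FAR1, a fatty acyl-CoA reductase, was 1.67-fold higher, NTRK3, a neurotrophin receptor, 1.67-fold, and the splicing factor SRSF11 1.66-fold.

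Among the lowest genes with the inhibitor were PEX11A, a peroxisomal membrane protein, at 1.73-fold lower, the tyrosine phosphatase PTPN7 at 1.70-fold lower, the Wnt ligand WNT11 at 1.64-fold lower, CYP2J2, an arachidonic acid epoxygenase, at 1.56-fold lower and the autophagy kinase ULK2 at 1.52-fold lower. Most of these were dim. On the inhibitor array, with a median of 4.16, PTPN7 was at 4.25, CYP2J2 at 4.42, WNT11 at 4.51, ULK2 at 4.76 and PEX11A at 5.40. At 1.5-fold, 28 genes were higher and 13 lower, while they were 36 and 8 after each array was centred on its median, 34 and 11 after quantile normalization, 57 and 56 with no filter on dim genes, which removed the excess of higher genes, and 5 and 0 with the offset of 64. The 2 probe sets of a gene correlated at 0.113 for this comparison. The other probe sets of RBL1 had a median log2 ratio of -0.36 in the authors' deposited table, against 0.97 on the probe set used, those of ACSL4 had -0.19 against 0.86, those of FAR1 -0.11 against 0.74, and that of PTPN7 0.04 against -0.77. For NTRK3, at 4.48 on the scrambled RNA array, the others had a median of 0.05 against 0.74, and for SRSF11 0.03 against 0.73.

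With the inhibitor 3 of 19 lists lay outside the range of random lists. The hypoxia and glycolysis genes had a median log2 ratio of -0.10, at percentile 0.20, and 17 of 20 lay below 0, among them ALDOC at -0.30, PFKFB4 at -0.28 and PDK1 at -0.23. The TGF-beta response genes had a median of 0.14 over 10 genes, at percentile 99.2, with KLF10 at 0.46 and TGFBI at 0.28. The NF-kB and inflammation genes had a median of 0.10 over 12 genes, at percentile 98.6, with IL1B at 0.46 and CXCL8, which encodes interleukin-8, at 0.39. IL1B lay near the cutoff, at 4.48 on the scrambled RNA array, and the other probe set of CXCL8 was at -0.01. None of these members passed 1.5-fold. After quantile normalization the hypoxia genes were at 0.19, the TGF-beta genes at 97.2 and the NF-kB genes at 97.4. The NF-kB genes were least stable, at 97.1 with no filter, 97.4 with the offset and 76.6, with a median of 0.02, with the mean of all probe sets. Over all genes of the authors' deposited table, with random lists not matched on signal, the 3 lists lay at percentiles 11.1, 94.1 and 61.5. All 3 lay outside on the opposite side in scrambled RNA over vector, with medians of 0.20, -0.21 and -0.38. That difference shares the scrambled RNA array, so a deviation of this array alone cannot be told apart from an effect of the inhibitor. It also sets an RNA against a plasmid transfection. Between both plasmid and both RNA arrays the 3 lists likewise lay outside, with medians of -0.13, 0.13 and 0.41. The opposite side in scrambled RNA over vector is therefore not particular to the scrambled RNA array.

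The published miR-663 targets had a median of -0.01 with the inhibitor, at percentile 60.5, and 5 of 10 lay above 0. JUND was at 0.23 with its remaining 2 probe sets at a median of -0.20, EEF1A2 at 0.21 and HSPG2 at -0.25. CXCR4, measured only in the authors' deposited table, had inhibitor ratios of 0.854, 0.738 and 0.673 and overexpression ratios of 1.21, 1.13 and 1.16. Medians and percentiles with the inhibitor were 0.06 and 93.6 for AP-1 genes, -0.02 and 36.6 for the cell cycle, -0.05 and 15.9 for cholesterol synthesis, -0.11 and 7.49 (1.21 with the offset) for colon epithelial differentiation, and -0.02 and 48.6 for epithelial-mesenchymal transition and invasion. They were 0.02 and 73.8 for the endoplasmic reticulum stress list, -0.05 and 13.8 for heat shock, 0.04 and 65.7 for histones, -0.01 and 63.8 for the interferon response, and 0.03 and 74.8 for the microRNA pathway. They were 0.01 and 47.7 for oxidative phosphorylation, 0.02 and 68.8 for p53 targets, 0.01 and 57.5 for ribosomal proteins and 0.01 and 61.1 for Wnt targets. Centring turned the sign of 4 and quantile normalization that of 5 of the 19 medians.

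**Figure D1:**
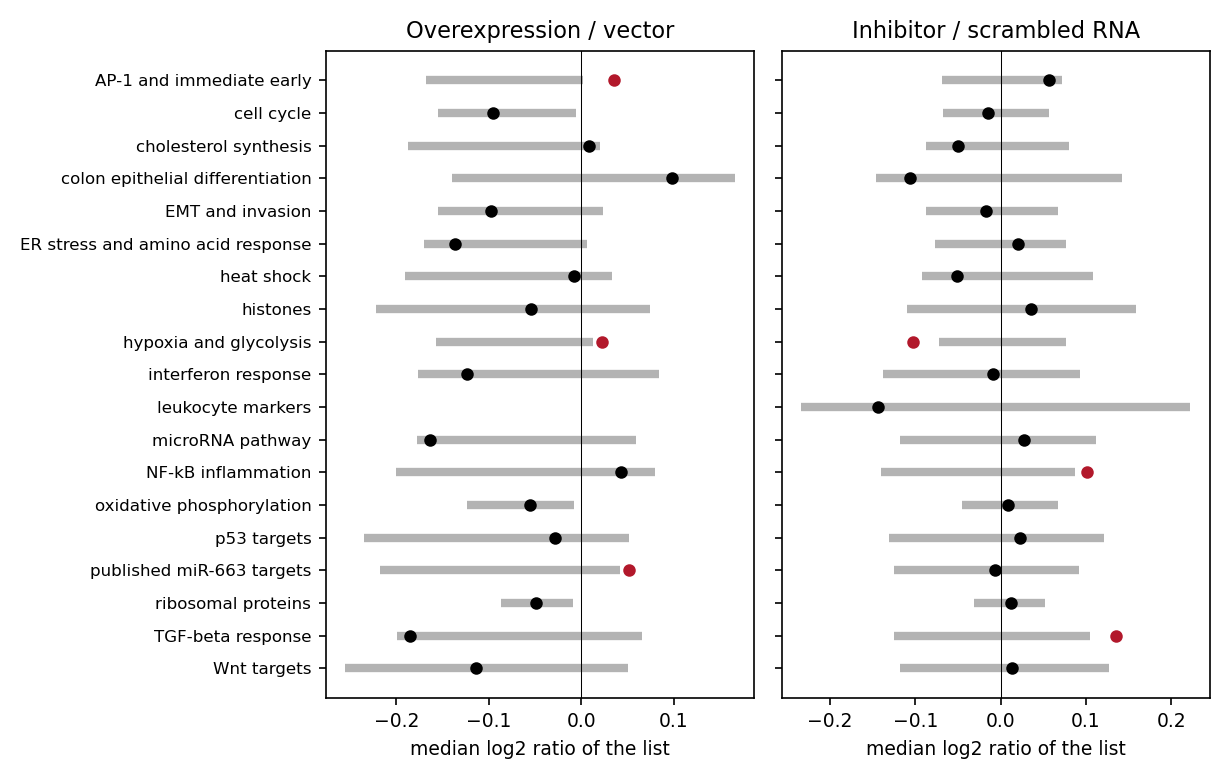
Median log2 ratio of each fixed gene list (points) for overexpression over vector (left) and inhibitor over scrambled RNA (right), with grey bars for the middle 95% of 10000 random lists matched on mean signal. Red points lie outside the bars, 3 in each comparison, and the hypoxia and glycolysis genes are the one list outside in both, at 0.02 and -0.10.

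The selection that the study describes joins both comparisons. At least 1.5-fold lower with overexpression and at least 1.5-fold higher with the inhibitor were 8 genes: RBL1, PPP1CB, MEIOC, TMEFF1, CYP51A1, ACSL4, RP2 and ZNF623. Independent lists of these sizes among 5392 genes would share 0.451 genes. CYP51A1, the lanosterol demethylase of cholesterol synthesis, was 1.75-fold lower and 1.60-fold higher. Its probe set is listed on chromosome 13 in the authors' deposited table, though the gene's band there is 7q21.2. Whether this probe set detects CYP51A1 was not examined. RP2, an activator of the GTPase ARL3, was 1.74-fold lower and 1.51-fold higher, and RBL1 was 1.71-fold lower and 1.96-fold higher. PPP1CB was 1.68-fold lower and 2.28-fold higher, and MEIOC, named for its role in meiosis, was 1.65-fold lower and 1.65-fold higher. TMEFF1, a transmembrane protein, was 1.60-fold lower and 1.66-fold higher, ACSL4 was 1.58-fold lower and 1.82-fold higher, and ZNF623 was 1.51-fold lower and 1.83-fold higher. The opposite selection held 1 gene, CRISPLD2, a secreted protein, at 1.60-fold higher with overexpression and 1.54-fold lower with the inhibitor, where independent lists would share 0.118. No gene passed 1.5-fold in the same direction in both comparisons.

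All 8 genes were also lower on the scrambled RNA array than on the vector array, by log2 differences from -1.06 for ZNF623 to -0.45 for ACSL4, with a median of -0.58. The selection itself favours this sign, since it takes genes high on the vector array and low on the scrambled RNA array. With equal levels and equal independent errors on all 4 arrays, the ratios of these genes would give a median of -0.74. The same holds in reverse for CRISPLD2, which was 1.71-fold higher on the scrambled RNA array than on the vector array. Of the 8, 7 had other probe sets in the authors' deposited table, and in 2 of them, PPP1CB and TMEFF1, the median of those leaned the same way in both comparisons, with log2 ratios of -0.41 and 0.24 for PPP1CB and -0.16 and 0.27 for TMEFF1. The medians went the opposite way in both for RP2, at 0.52 and -0.44, and ACSL4, at 0.13 and -0.19. For MEIOC they were 0.00 and -0.11, and for RBL1 and CYP51A1 they went the opposite way with the inhibitor. With an offset of 64 on the linear scale 2 genes passed, and with the sign of the titles 0.

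**Figure D2:**
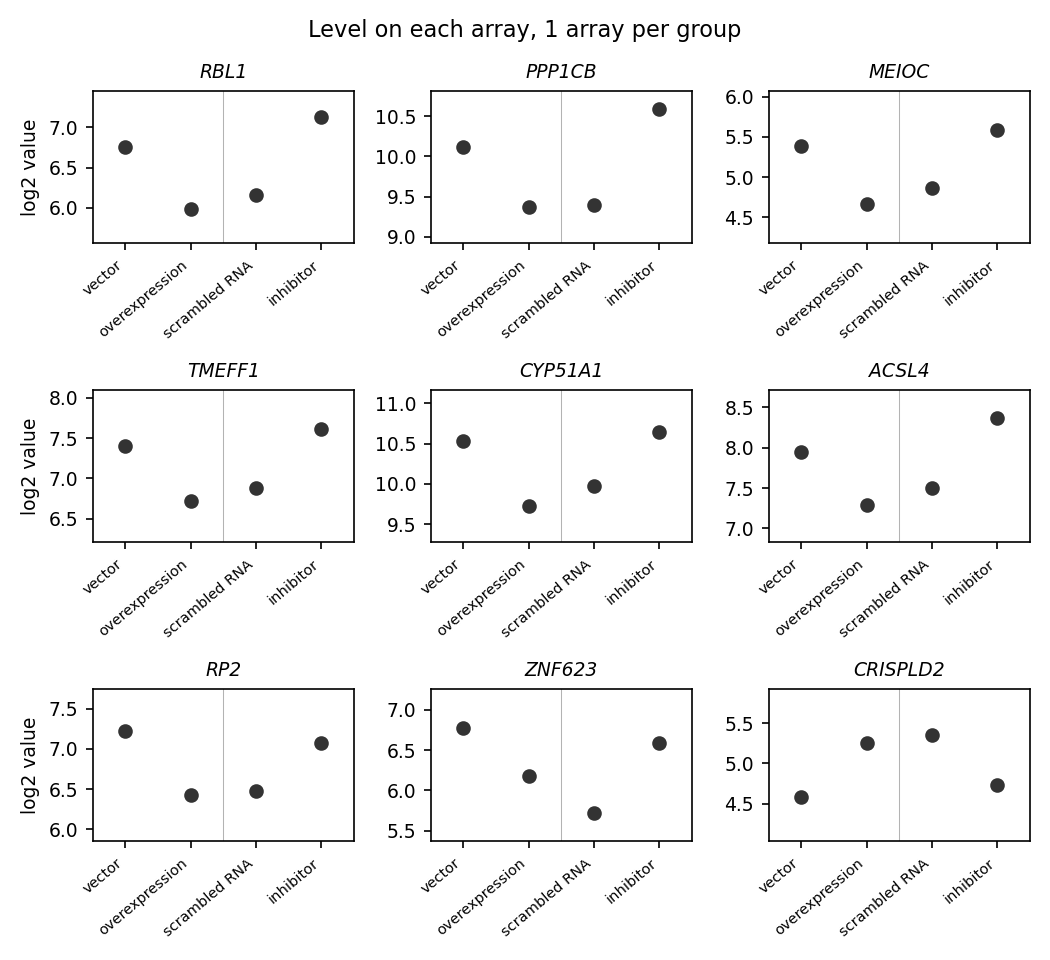
Log2 value of the 8 genes lower with overexpression and higher with the inhibitor, and of CRISPLD2, on each of the 4 arrays; each point is 1 array and every panel spans the same log2 range. The scrambled RNA array lies below the vector array for the 8 genes, by 0.45 to 1.06 log2 units, and above it for CRISPLD2, a sign that the selection of these genes itself favours.

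Over the 42450 probe sets of the authors' deposited table, 75 were lower and higher in this order by 1.5-fold, where independent lists would share 5.51, and 43 went the opposite way, where 5.35 would be shared. One probe set was lower and 2 were higher in both. A single probe set passed 2-fold in both, in MALAT1 on chromosome 11 at positions 65266811 to 65267534 (genome build not given in the sources used here), with an overexpression ratio of 0.294 and an inhibitor ratio of 2.61. Of the 12 MALAT1 probe sets, 8 had an overexpression ratio under 1 and 4 over 1, the latter from 1.11 to 1.30, and 10 had an inhibitor ratio over 1, while 6 were under 1 and over 1 in this order. The table lists 5 of the 12 on the minus strand and 7, with the probe set above, on the plus strand, and 3 of the 4 with overexpression ratios over 1 are on the minus strand. The remaining minus-strand probe sets had overexpression ratios of 0.601 and 0.611, so strand did not separate the directions. Whether the minus-strand probe sets detect MALAT1 was not examined. KLF5, an intestinal transcription factor on chromosome 13 chosen after its values were seen, had a probe set at 0.393 and 1.96 and a second one at 0.782 and 0.992. Averaged per gene, 7 genes passed in this order and 15 in the opposite one. Of the 75 probe sets lower and higher in this order, 67 named 1 gene each, and these fell in 64 genes. Among the 64 genes, 2 had several such probe sets, AZI2 and MALAT1. Their overexpression ratios were 0.635 and 0.575 in AZI2, and 0.294, 0.421 and 0.611 in MALAT1, the last on a probe set listed on the minus strand.

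Across 5392 genes the 2 comparisons were inversely related, with a Pearson correlation of -0.346 and a Spearman correlation of -0.340. Genes are not independent replicates, and the titles' assignment would give 0.346. Over all 8794 named genes split into 5 groups by mean signal, the correlation went from -0.158 in the dimmest group to -0.639 in the brightest. The relation was mostly within single probe sets: over 10743 genes with several probe sets in the authors' deposited table, the covariance between one probe set's overexpression ratio and another probe set's inhibitor ratio was 0.170 of that within probe sets, with a 95% bootstrap interval over genes from 0.119 to 0.217. In the value table, over 1352 genes, it was 0.249, from 0.158 to 0.340.

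**Figure D3:**
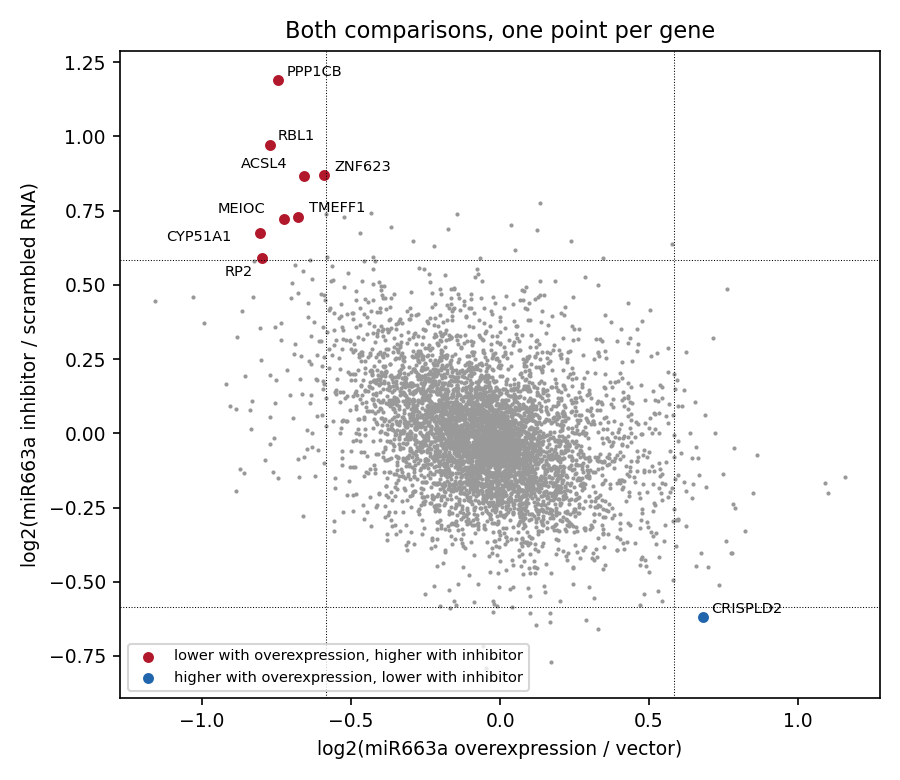
Log2 ratio of overexpression over vector (horizontal) against log2 ratio of inhibitor over scrambled RNA (vertical), with 1 point for each of 5392 genes above the median signal on the arrays compared; dotted lines mark 1.5-fold. The cloud runs from upper left to lower right, with 8 genes past both lines at upper left and 1 at lower right.

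As background, the scrambled RNA array was set against the vector array, which compares an RNA with a plasmid transfection. Of 5513 genes, 6 were at least 2-fold lower with scrambled RNA and 0 higher, and at 1.5-fold 106 were lower and 24 higher (79 and 36 after centring), so the controls differed in about as many genes as overexpression and vector did. The neutrophil-attracting chemokine gene CXCL8 was 7.08-fold lower, ZMYM5 2.91-fold lower, GIGYF2, a translational repressor, 2.34-fold lower, UPP1, a uridine phosphorylase, 2.32-fold lower, the chemokine gene CXCL1 2.11-fold lower and ZNF623 2.08-fold lower. SPATA13 was the highest, at 1.94-fold. The stress gene GADD45A was 1.91-fold lower, KLF10, a gene induced by TGF-beta, 1.94-fold lower and THBS1 1.92-fold lower.

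In this background 7 of 19 lists lay outside the range of random lists, more than in either comparison of the design. The endoplasmic reticulum stress and amino acid response genes had a median of -0.42, below all random lists, the NF-kB and inflammation genes -0.38 at percentile 0.025, the TGF-beta response genes -0.21 at 1.15, the AP-1 genes -0.11 at 2.24 and the fibroblast markers -0.23 at 2.06. The hypoxia and glycolysis genes had a median of 0.20, above all random lists, with 18 of 20 above 0, and the oxidative phosphorylation genes 0.06 at percentile 98.6.

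**Figure D4:**
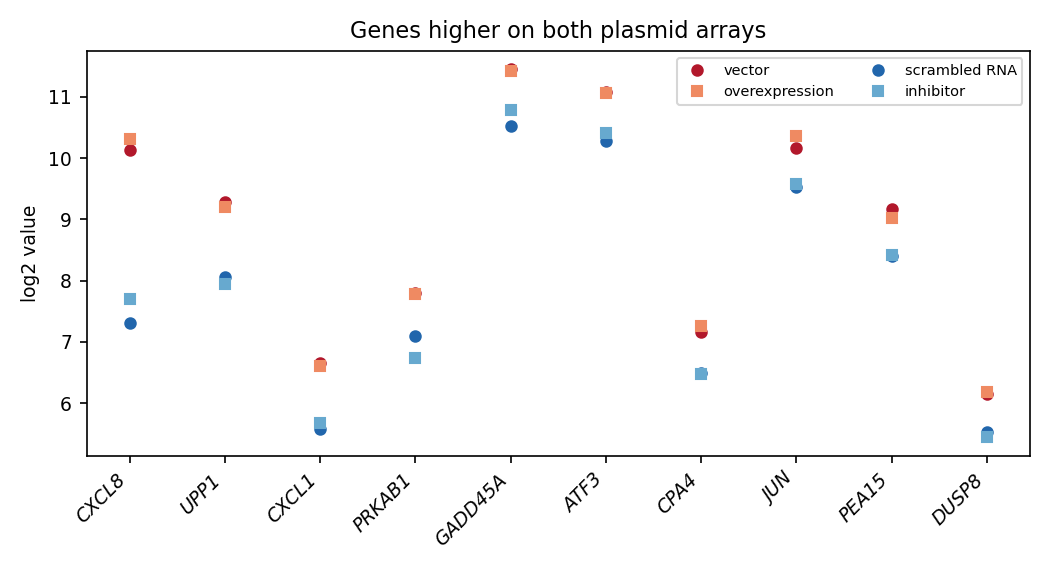
Log2 value on each of the 4 arrays (points, 1 array each) for the 10 genes with the widest mean difference among the 12 whose lower plasmid array lay at least 1.5-fold above the higher RNA array. CXCL8 has the widest gap, with 10.13 and 10.31 on the vector and overexpression arrays and 7.31 and 7.70 on the scrambled RNA and inhibitor arrays.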

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

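Both results here come from the score column of the authors' deposited table, which the comparisons do not use. It is the sum of squared deviations of the 4 log2 values, and with the part due to the 2 ratios removed it leaves the size, without its direction, of the difference between the plasmid arrays and the RNA arrays. The tests of the MAP2K5 probe set were chosen after its value was seen.

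A probe set of MAP2K5, the kinase upstream of ERK5, on chromosome 15, had the widest difference between plasmid and RNA arrays of all 42450 probe sets, at 4.96 log2 units or 31.0-fold. In the authors' deposited table its overexpression ratio was 3.97 and its inhibitor ratio 0.729. A change of MAP2K5 RNA as a whole is argued against by the remaining 5 MAP2K5 probe sets, which differed between plasmid and RNA arrays by at most 0.117 log2 units. That holds only as far as these 5 detect MAP2K5 RNA, which was not examined. Among them, 1 is listed on the minus strand. A candidate explanation that stays open is plasmid sequence bound by the probe set with the wide difference, since neither probe nor plasmid sequences were used here and the 4.96 log2 units cannot decide it. A transcript form seen by that probe set alone was not tested.

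A probe set of CXCL8 had the next widest difference obtained in this way, at 2.96 log2 units. It is a different probe set from the one with levels on all 4 arrays, where the plasmid arrays were higher by 2.71 log2 units or 6.56-fold.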

How the results depend on the processing

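No paired analysis was possible because each group has 1 array. The planned seed site comparison was not run, since 3′ untranslated sequences were not used here. Detection calls were not used, so signal over background was judged by the array median alone. The counts from the authors' table were chosen after the data were seen.

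The stricter filter and 50 signal bins kept each count within 1.5 times its main value, and the correlation stayed between -0.26 and -0.48 with the sign used. The cause of the shifts was not tested, except that a lower threshold, no filter or more probe sets admit more values and the offset shrinks ratios of dim genes. For overexpression, the genes 2-fold higher (3) and lower (2) became 51 and 90 at 1.5-fold, 18 and 31 per probe set of the authors' table and 6 and 6 per gene there. The higher count was 6 with no filter, 0 with the offset of 64 and 1 with the mean of probe sets. The lower count was 1 after centring, 1 after quantile normalization and 0 with the offset of 64. For the inhibitor, the 1 higher and 0 lower became 28 and 13 at 1.5-fold, 4 and 2 per probe set of the authors' table, and 0 and 1 with the sign turned. The higher count was 2 after centring and 0 with the mean of probe sets, and the lower count was 1 with no filter and 1 per gene of the authors' table. For the controls, 0 higher and 6 lower became 24 and 106 at 1.5-fold, and the lower count was 10 with no filter and 2 with the offset.

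The 8 genes lower with overexpression and higher with the inhibitor became 2 with the offset of 64, 75 per probe set of the authors' table, 0 at 2-fold and 0 with the sign turned, which reversed the correlation to 0.346. The 3 lists outside the range of random lists with overexpression became 5 with no filter and 5 with the offset. There were also 4 outside in the authors' table, none of them among the 3: the cell cycle genes at percentile 1.14, the endoplasmic reticulum stress genes at 0.07, colon epithelial differentiation at 99.7 and leukocyte markers at 99.8. The 3 with the inhibitor became 1 after quantile normalization and 0 in the authors' table. Random lists for that table were not matched on signal. The turned sign reverses every inhibitor value. Under the alternatives run on the 370 named gene values, which leave it out, none past 1.5-fold changed sign. Sizes moved for 101 in the gene means of the authors' table, 90 with the offset and 28 with the mean of probe sets.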

Other observations

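The tests in this part of the inverse ratios and of the plasmid against RNA difference were chosen after the results were seen.

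Among genes above the median signal, most wide gaps between pairs of arrays followed the kind of molecule delivered. Over all probe sets only the RNA arrays grouped in this way, with the highest correlation, 0.9967, while the plasmid arrays correlated at 0.9958, below vector with scrambled RNA at 0.9961 and with the inhibitor at 0.9964. With plasmid, 12 of 5392 genes lay at least 1.5-fold above both RNA arrays on both plasmid arrays, and 2 lay below. CXCL8 was 6.56-fold higher, UPP1 2.36-fold and CXCL1 2-fold, followed by PRKAB1, a subunit of the energy sensor AMPK, at 1.84-fold, GADD45A at 1.73-fold, and the stress and AP-1 transcription factors ATF3 at 1.66-fold and JUN at 1.64-fold. CPA4, PEA15, DUSP8 and NFIL3 were 1.53-fold to 1.65-fold higher. The neuronal calcium sensor VSNL1 was 1.57-fold lower and FBXO9 1.58-fold lower, but the remaining 8 probe sets of FBXO9 differed by a median of 0.212 log2 units against 0.663, without direction, and neither gene kept the 1.5-fold gap after quantile normalization (0.57 log2 units each). The corresponding counts were 3 for overexpression and scrambled RNA against vector and inhibitor, and 0 for the remaining split.

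In the plasmid against RNA difference 6 of 18 gene lists lay above the range of random lists and 3 below it. NF-kB and inflammation genes had a median of 0.41, endoplasmic reticulum stress genes 0.21 and AP-1 genes 0.14, each above all random lists, the interferon response genes 0.23 with 11 of 12 above 0, p53 targets 0.20 and TGF-beta response genes 0.13. Cell cycle genes had a median of -0.15, oxidative phosphorylation genes -0.12, with 23 of 25 below 0, and hypoxia and glycolysis genes -0.13.

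For the 12 genes higher with plasmid, single deviating probe sets are argued against in the 4 genes with another tested probe set. Their tested others differed by a median of 0.598 log2 units, with PRKAB1 the lowest at 0.47. With every other probe set of the authors' table, sizes without direction had a smaller median for ATF3, 0.326 over 2, and for JUN, 0.480 over 3. Single deviating probe sets are also argued against in CXCL8, whose other probe set differed by 2.96 log2 units (direction not known). This explanation stays open for DUSP8, with 0.447 on its other probe set, also without direction, and for the 6 genes with no other probe set. Scaling by signal level is argued against as the whole cause, since after quantile normalization 10 of the 12 kept the gap. A handling difference between the plasmid and the RNA experiments cannot be told apart from a response of the cells to plasmid, since delivery and handling coincide for all 12 genes. A response to transfected DNA may be a biological candidate, and it was not tested.

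The inverse relation of the comparisons may come from several sources. Opposite changes of whole transcripts are argued against as its main source by the covariance between probe sets of a gene. It was 0.170 of that within probe sets (0.249 in the value table, and 0.150 where all probe sets of a gene are listed on 1 strand). For 57 candidate genes, the other probe sets had medians of -0.13 (95% bootstrap interval -0.19 to -0.05) with overexpression and -0.01 with the inhibitor. The called ones had -0.73 and 0.70, but they were selected by size, which itself favours smaller values on the others. This contrast is therefore no argument of its own. A part may be shared, since 39.9% of these other probe sets lay under 0 and over 0 in this order, against 28.1% of all probe sets, beside the 0.170 above. Scaling by signal level is argued against by a correlation of -0.351 after quantile normalization. A difference in RNA ends between arrays is consistent with the data: of the 42 called probe sets in genes whose probe sets have different 3′ ends by the positions in the authors' table, 73.8% were the 3′-most (exact 95% interval 58.0% to 86.1%), where 38.8% would be by position alone, and of the 19 called in the opposite order 31.6% were (12.6% to 56.6%, with 35.6% by position). Over 7857 genes, though, the 3′-most minus the 5′-most ratio had a median of only -0.04 with overexpression and 0.03 with the inhibitor, so the size for the called probe sets stays unexplained, and a change of 3′ ends by miR663a stays open as an untested biological explanation.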
